A study of Mus musculus with 10 samples.

How the data were processed

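Total RNA of whole ovaries from 3-week-old mice of a mixed C57/Bl6/N;129SvEv7 strain was made into TruSeq libraries and sequenced on a NovaSeq instrument, per the labels' protocols. The labels divide the libraries into 5 controls and 5 named Uba3 cKO, and each column of the table was matched to its sample by the name given in the labels. The tools named are fastp, STAR, featureCounts and DESeq2 with the genome build GRCm39, per the submitters' processing notes, which give neither versions nor the part each tool played. The deposited values are on a log2 scale, from -0.21 to 20.19, with 1 value per gene and library for 22891 Ensembl genes. The authors' table does not name its transform. The median SD over the 10 libraries was 0.0425 for genes with means below 2, 0.085 from 2 to 4, 0.153 from 4 to 6, 0.174 from 6 to 8 and 0.132 from 8 to 10. The median SD thus fell from means of 6 to 8 toward lower means. Lower genes appear drawn toward their mean, most clearly those with means below 4, most of them under the filter below. Differences of genes with means up to 6 may be understated, most so near the filter, and folds are 2 to the power of a difference on this scale. No counts could be recovered, so the depth per library and the counting error are unknown, and neither a count test nor a pseudocount applied. The design fixed before the data were examined had assumed linear normalized values; the same tests were run on the deposited log2 values instead.

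Symbols were found for 22188 of the 22891 identifiers. Positions, transcript lengths, transcript sequences and gene classes came from GENCODE M21, which is built on GRCm38 and not on the build in the notes, so they were used only for names, neighbourhood, length and sequence matches, and no positions are given. No pair of libraries had identical columns.

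Genes with a mean of at least 10 on the linear scale (3.32 on the log2 scale) were kept, which left 15629. Groups were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend in the empirical Bayes step, no covariate, and Benjamini-Hochberg adjustment with a threshold of 0.05. Standard errors, 95% intervals and p-values of genes come from this fit. Single values such as Uba3 or a list mean were compared with an exact two-sided permutation test of the difference in means, whose smallest p with 5 against 5 is 0.00794. Tests of genes were checked on 20 simulations from the libraries' own residuals. In each, 200 genes with a mean of at least 8 were shifted, so recovery of lower genes was not checked. Of genes shifted by 0.25 log2 units 15.5% were recovered, with 78.9% at 0.5, 99.1% at 1 and 99.9% at 2. Other calls among the 15629 genes had a median of 1 and a highest count of 47. The residuals were not rescaled for the fitted group means, so these rates may be too high. Shifting 200 genes together also eases the adjusted threshold for each, so the rates do not hold for a few changed genes alone. In 20 simulations of list tests, 20 of 20 lists of 20 genes shifted by 0.3 and 2 of 20 unshifted lists had p under 0.05. These lists were drawn at random from genes with a mean of at least 8. Members of the fixed lists can vary together, with an estimated correlation of 0.544 for the mitochondrially encoded list. The simulations therefore did not check the preset correlation for lists of that kind.

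Before the data were examined, 30 gene lists were fixed, 16 of pathways and 14 of cell types, with 473 members. Of these 467 were found, 7 of them through a synonym, and members that were not matched are not analysed here. Lists were compared with camera with a preset correlation of 0.01, adjusted over the 30 lists, and again with the correlation estimated from the data, with fry, and with an exact permutation test of the list mean. By fry 0 lists were called (smallest adjusted p = 0.986), and the smallest adjusted p of the permutation tests was 1. Since their smallest possible p is 0.00794, a single list could not pass adjustment over 30 lists in the permutation tests. The rule for named genes, also fixed beforehand, took Uba3; up to 12 genes in each direction among those past the threshold with a mean of at least 50 and no overlap, of which there were none; and from each list up to 4 members past the threshold or, where none passed, the 2 with the smallest p. Of the genes this rule takes, 1 is not reported here. Other genes are named with a remark that they were chosen after their values were seen.

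Library properties were summarised as the mean of the 49 tested oocyte markers and as the slope of a library's deviations on log2 transcript length over 9182 genes with a mean of at least 8 and a known length. Genes at 2 levels were those with a gap of at least 1 log2 unit, at least 3 times the SD within the levels, and at least 2 libraries on each side. Their longest transcripts were searched against all transcripts with blastn 2.17.0, and a hit to another gene with at least 95% identity over at least 50% of the transcript counted as near-identical. Each was matched to the 5 nearest other genes by mean level.

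Alternatives were no filter, a mean of at least 50, TMM-type scaling (own implementation, trimming 30% and 5%), upper-quartile scaling, robust empirical Bayes, library quality weights, a block on the replicate number, an estimated correlation, and leaving out each library in turn. The oocyte marker mean and the length slope as covariates, and counts at unadjusted p, were added after the data were seen. Pseudocounts other than 1 and count tests with edgeR and DESeq2 had been planned and were not used, because the values are already log2 and hold no counts. Data handling and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.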

Results

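RNA was sequenced from whole ovaries of 3-week-old mice that had not received hormone stimulation. The series held 5 control ovaries and 5 ovaries labelled Uba3 cKO. Uba3 encodes the catalytic subunit of the enzyme that activates NEDD8, a small ubiquitin-like protein whose best-known targets are the cullin scaffolds of ubiquitin ligases. The series title places the comparison in a study of neddylation, transcription in mitochondria and the quality of oocytes. The deposited table gave 1 log2 value for each of 22891 genes in each of the 10 libraries. Library medians lay between 6.29 and 6.44 log2 units, and the sequencing depth behind the values is unknown. Nothing beyond the labels' wording says that the ovaries came from separate animals, so the p-values measure the spread between these samples.

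Follicle transcripts were among the most abundant in both groups. Inha, which encodes the alpha subunit of inhibin, averaged 16.61 ± 0.079 (SD, n = 5) in control ovaries and 16.67 ± 0.12 (SD, n = 5) in ovaries labelled Uba3 cKO. Gja1, the connexin that joins granulosa cells, stood at 16.02 ± 0.12 in controls and differed by -0.023 (standard error 0.12). Amh, the anti-Müllerian hormone of growing follicles, stood at 13.74 ± 0.32 and 13.82 ± 0.16. Gdf9, a growth factor secreted by the oocyte, stood at 12.30 ± 0.30 and 12.24 ± 0.30. Cyp19a1, the aromatase of larger follicles, was far lower at 7.56 ± 0.37 and 7.50 ± 0.57. These 5 genes were chosen after their values were seen, to describe the tissue.

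The targeted gene was measured first. Uba3 (ENSMUSG00000030061, on chromosome 6) had a level of 10.12 ± 0.18 (SD, n = 5) in control ovaries and 10.12 ± 0.069 (SD, n = 5) in ovaries labelled Uba3 cKO. The log2 difference was 0.0032 with a standard error of 0.081 and a 95% interval from -0.17 to 0.18, which bounds the fold between 0.887 and 1.13 (exact two-sided permutation test, p = 1). Control values ran from 9.88 in replicate 3 to 10.37 in replicate 4. Values under the Uba3 cKO label ran from 10.02 in replicate 4 to 10.22 in replicate 5. The labels name neither the deleted exons nor the cells in which the gene was deleted, and a gene-level value in a whole organ does not resolve either. The level of Uba3 therefore did not check the labels, and groups are named here as labelled.

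**Figure D1:**
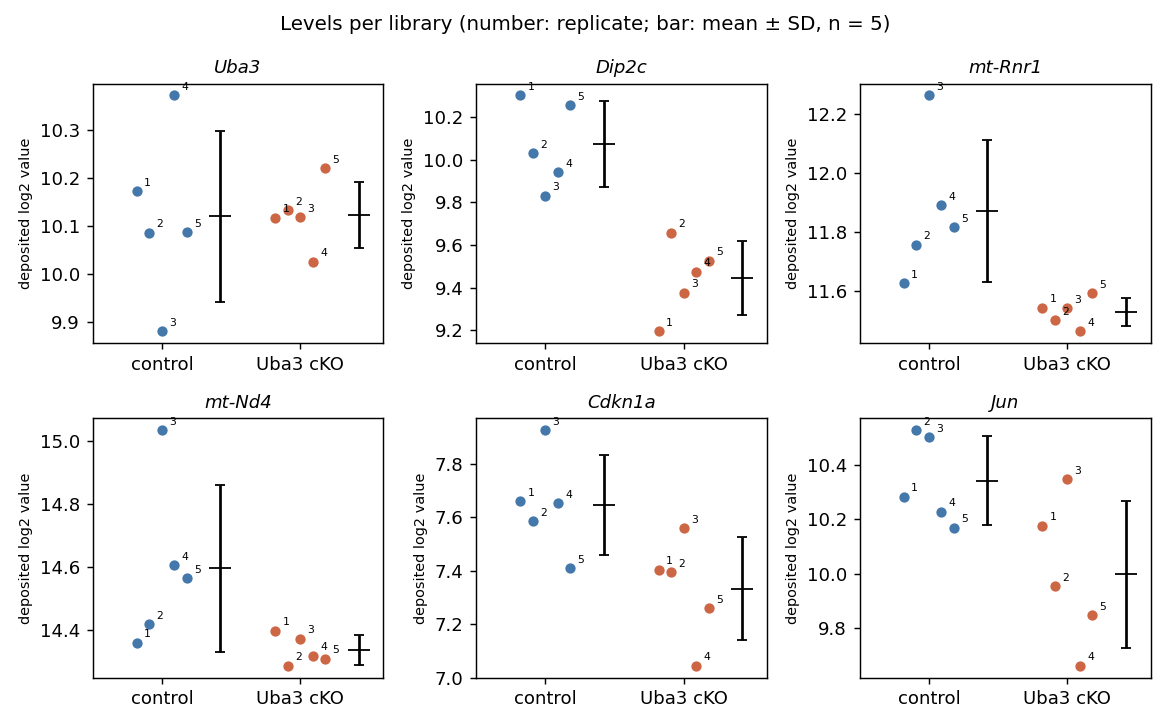
Deposited log2 values of 6 genes in each library of the control group (blue) and the Uba3 cKO group (orange), with the replicate number beside each point and the mean ± SD (n = 5) as a bar; each panel has its own axis, which does not start at 0. Uba3 overlaps between groups at 10.12 in both, whereas Dip2c and mt-Rnr1 are lower in all 5 libraries labelled Uba3 cKO without passing adjustment over all genes.

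No gene passed adjustment over all genes in the comparison of ovaries labelled Uba3 cKO with controls. Dip2c (ENSMUSG00000048264), a disco-interacting protein family member, had the smallest p of all genes, with 10.07 ± 0.20 (SD, n = 5) in controls and 9.45 ± 0.17 (SD, n = 5) under the Uba3 cKO label. Its log2 difference was -0.62 (standard error 0.11), lower in 5 of 5 libraries than every control, with an adjusted p of 0.621 by limma. Trim6, a tripartite-motif ubiquitin ligase, stood at 5.65 ± 0.16 and 6.13 ± 0.069, a log2 difference of 0.49 (standard error 0.088, adjusted p = 0.621). Drc1, a part of the dynein regulatory complex of cilia, differed by 0.39 (standard error 0.072, adjusted p = 0.621), and Nfkbiz, a nuclear regulator of NF-kappa-B, by 0.49 (standard error 0.10, adjusted p = 1). These 4 genes fall outside the rule for named genes and were chosen after their values were seen.

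Of 15629 genes tested with limma, 0 passed an adjusted p of 0.05, so 0 were called at a 2-fold change. At an unadjusted p under 0.05 there were 280 genes, 152 with the higher mean under the Uba3 cKO label and 128 with the lower, against 781.5 by chance. The groups did not overlap in 50 genes, 0.320% of those tested, where chance gives 0.794%. Among the 9207 genes with a mean level of at least 8, the 95% interval of the difference lay within 1 log2 unit either side of 0 for 9191 and within 0.5 for 8854, which is 96.2%. These intervals bound levels in whole ovaries, not changes confined to some of the cells. Deposited values had a median SD over the 10 libraries of 0.085 for means from 2 to 4, 0.153 from 4 to 6 and 0.174 from 6 to 8. Differences of genes with means up to 6 may therefore be understated, most so near the filter. With the libraries' slope on transcript length as a covariate, an alternative chosen after seeing the data, Dip2c alone was called (log2 difference -0.67, adjusted p = 0.0142).

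**Figure D2:**
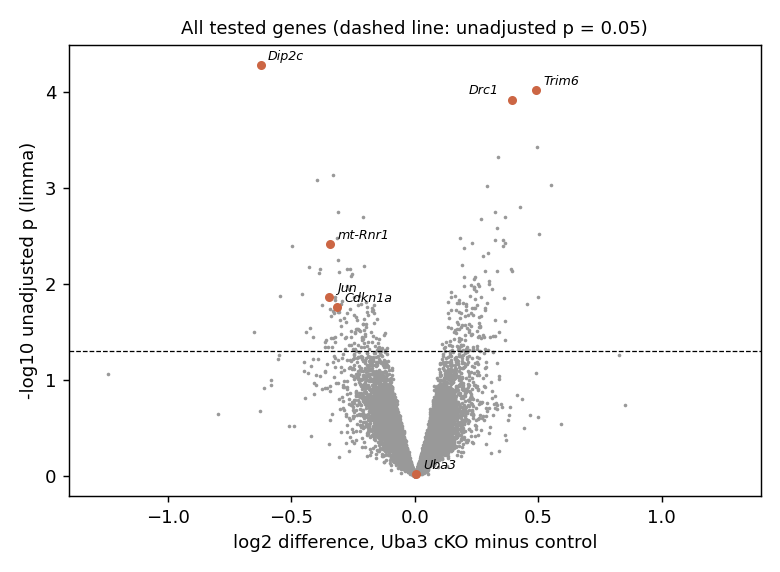
Each of the 15629 tested genes by its log2 difference between Uba3 cKO and control (horizontal) and the -log10 of its unadjusted limma p (vertical), with an unadjusted p of 0.05 as the dashed line. Dip2c, Trim6 and Drc1 have the smallest p and an adjusted p of 0.621, and Uba3 lies at a difference of 0.0032.

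Components of the neddylation pathway had closely matching levels in the groups. Of 31 members, which include NEDD8, its conjugating enzymes, the cullins and the COP9 signalosome, 19 had the higher mean under the Uba3 cKO label and 12 the lower. Rbx1, the RING subunit that docks NEDD8 enzymes onto cullins, stood at 10.64 ± 0.15 in controls and 10.54 ± 0.088 under the Uba3 cKO label. Senp8, a protease that matures NEDD8, stood at 8.30 ± 0.037 and 8.22 ± 0.060. The mean difference of the list was -0.0047 and its median 0.0084, so the sign differed between them (camera adjusted p = 0.885). No member passed the limma test over all genes or adjusted over the list alone, and 0 were at an unadjusted p under 0.05.

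Transcripts of the mitochondrial genome had lower means under the Uba3 cKO label. All 12 tested mitochondrially encoded protein genes did, with a list level of 11.60 ± 0.24 (SD, n = 5) in controls and 11.38 ± 0.034 (SD, n = 5) under the Uba3 cKO label, a fold of 0.854. In controls, single genes of the list ran from 4.66 for mt-Nd4l to 17.45 for mt-Co1. The genes mt-Co2, mt-Atp6, mt-Co3 and mt-Nd3 lay between 6.47 and 7.39. The list level is thus a mean over very unlike levels, whose source was not tested. The list fell by 0.23 on the log2 scale with a preset correlation between its genes (camera, adjusted p = 2.34e-09). The call was lost with adjusted p = 0.587 with an estimated correlation, and an exact permutation test of the list mean gave p = 0.0556. The mt-Nd2 and mt-Nd4 genes encode subunits of complex I. mt-Nd2 stood at 14.38 ± 0.24 and 14.14 ± 0.072, and mt-Nd4 at 14.60 ± 0.26 and 14.34 ± 0.046. Of the 12 genes, 3 (mt-Nd2, mt-Nd4 and mt-Co3) were at an unadjusted p under 0.05 by limma and 0 passed adjusted over the list alone.

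The ribosomal RNAs of mitochondria went the same way as the protein genes. The mt-Rnr1 transcript (ENSMUSG00000064337), the small ribosomal RNA, stood at 11.87 ± 0.24 (SD, n = 5) in controls and 11.53 ± 0.049 (SD, n = 5) under the Uba3 cKO label. Its log2 difference was -0.34 (standard error 0.098), with all 5 libraries below every control (exact two-sided permutation p = 0.00794, the smallest this design allows; limma adjusted p = 1). The large ribosomal RNA, mt-Rnr2, differed by -0.34 (standard error 0.13, exact permutation p = 0.0159, limma adjusted p = 1), and without control replicate 3 by -0.20. Of 9 tested mitochondrial tRNAs, 8 had the lower mean and 1 was at an unadjusted p under 0.05 by limma. Their log2 differences ran from -0.32 for mt-Tc to 0.013 for mt-Ty, with mt-Te, mt-Tl2, mt-Th and mt-Ts2 between -0.083 and -0.003. These RNAs were added after their values were seen. Control replicate 3 had the highest value of the protein list, 0.49 above the mean of all libraries, and also the steepest length slope, and without it the list difference was -0.13 (exact permutation p = 0.0714; camera adjusted p = 6.03e-05 with the preset correlation), mt-Nd2 differed by -0.15 and mt-Nd4 by -0.15.

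**Figure D3:**
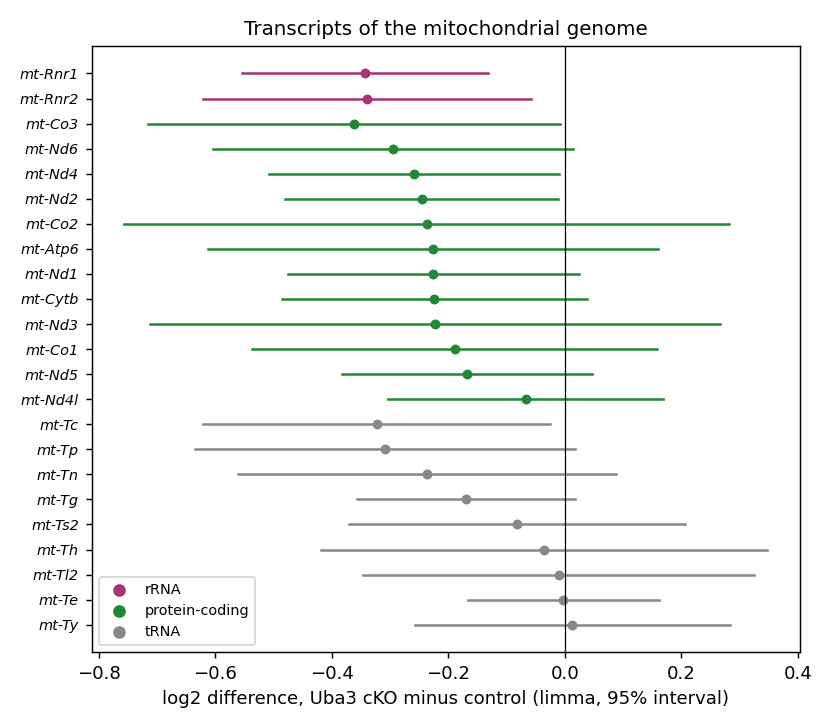
Log2 difference between Uba3 cKO and control (point) with its 95% interval by limma (line) for the 23 tested transcripts of the mitochondrial genome, coloured by class. Points lie left of 0 for both ribosomal RNAs, all 12 protein genes and 8 of 9 tRNAs, and no transcript passed adjustment over all genes.

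Nuclear genes that serve mitochondria formed 3 lists, none of them called in the comparison. Among 23 genes of mitochondrial transcription and replication, 10 had the higher mean under the Uba3 cKO label and 13 the lower (mean difference -0.0090, camera adjusted p = 0.868). Tfam, which packages mitochondrial DNA and takes part in starting its transcription, stood at 10.02 ± 0.086 and 10.06 ± 0.034, and Polrmt, the mitochondrial RNA polymerase, at 9.67 ± 0.064 and 9.72 ± 0.047; both were chosen after their values were seen. Esrra, an orphan nuclear receptor, stood at 8.23 ± 0.12 and 8.38 ± 0.13, and Ssbp1, a single-stranded DNA binding protein, at 9.56 ± 0.089 and 9.46 ± 0.12. The nuclear-encoded respiratory chain had a mean difference of -0.032 over 42 genes (camera adjusted p = 0.242), with Ndufb8 at 7.30 ± 0.24 and 7.09 ± 0.19 and Cox6c at 11.53 ± 0.15 and 11.36 ± 0.25. The respiratory chain was called in 4 of 19 alternative settings, without control replicate 2 or Uba3 cKO replicate 1, 3 or 5. Its difference turned to 0.0061 without control replicate 3 and to 0.0048 without Uba3 cKO replicate 4. The mitochondrial ribosome had the lower mean under the Uba3 cKO label in 20 of 24 genes, with a mean difference of -0.042 (camera adjusted p = 0.0634; adjusted p = 0.974 with an estimated correlation). With the preset correlation it was called in 8 of 19 alternative settings: without a filter, with a mean of at least 50, and without control replicate 1, 2 or 5 or Uba3 cKO replicate 1, 3 or 5, whereas without control replicate 3 its difference turned to 0.0038. Its examples were Mrpl13 at 10.02 ± 0.092 and 9.91 ± 0.10 and Mrpl10 at 9.95 ± 0.14 and 9.84 ± 0.085. In these 3 lists 0 genes passed limma over all genes or adjusted over the list alone, and 0 were at an unadjusted p under 0.05.

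Targets of p53 and genes of the early stress response were the other lists called with the preset correlation. The p53 targets fell by 0.10 on the log2 scale, with the lower mean in 12 of 15 genes (camera adjusted p = 0.00376), a call that was lost with adjusted p = 0.587 with an estimated correlation. Cdkn1a, the cell cycle inhibitor p21, stood at 7.65 ± 0.19 (SD, n = 5) and 7.33 ± 0.19 (SD, n = 5), and Phlda3, an inhibitor of Akt signalling, at 8.71 ± 0.21 and 8.38 ± 0.36. Without Uba3 cKO replicate 4 the p53 difference was -0.069 (adjusted p = 0.113). The immediate early and heat shock list fell by 0.16, with the lower mean in 14 of 16 genes (camera adjusted p = 4.33e-05). This call was lost too, with adjusted p = 0.913 with an estimated correlation. Jun stood at 10.34 ± 0.16 in controls and differed by -0.35 (standard error 0.12), and Fos stood at 8.72 ± 0.24 and 8.36 ± 0.35; both encode subunits of the AP-1 transcription factor. Without control replicate 3 the early list differed by -0.094 (adjusted p = 0.161). In the p53 list 1 gene and in the early list 2 genes were at an unadjusted p under 0.05 by limma, and 0 passed adjusted over the list alone.

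Other stress and signalling lists were not called. The integrated stress response had a mean difference of -0.025 over 18 genes (camera adjusted p = 0.601); Chac1, which degrades glutathione, stood at 4.51 ± 0.16 and 4.32 ± 0.068, and Phgdh, the first enzyme of serine synthesis, at 10.70 ± 0.11 and 10.83 ± 0.17. Targets of NRF2 differed by 0.034 over 14 genes (camera adjusted p = 0.242), with Nqo1 at 5.50 ± 0.076 and 5.63 ± 0.097 and Gsta4 at 8.71 ± 0.18 and 8.85 ± 0.21. The NRF2 list was called in 1 of 19 alternative settings, with library quality weights. The TGF-beta and BMP response list differed by -0.085 over 15 genes (camera adjusted p = 0.116). It was called in 4 of 19 alternative settings: the replicate block, and without control replicate 4 or 5 or Uba3 cKO replicate 3. Leaving out 1 library, its difference ran from -0.13 without control replicate 5 to -0.046 without control replicate 1. The inhibitory Smads of the list had values of 10.39 ± 0.19 and 10.14 ± 0.24 for Smad7 and of 9.41 ± 0.27 and 9.13 ± 0.22 for Smad6. The interferon response differed by -0.00070 over 10 genes (camera adjusted p = 0.895), with the opposite sign in the test statistic, and held Usp18 at 4.50 ± 0.11 and 4.59 ± 0.048. Genes of the ovulatory response differed by 0.025 over 7 tested genes (camera adjusted p = 0.601), with Cited4 at 7.72 ± 0.34 and 7.56 ± 0.15 and Ptx3 at 5.33 ± 0.16 and 5.44 ± 0.21.

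Division and metabolism also showed no called list. Genes of mitosis differed by 0.034 over 16 genes (camera adjusted p = 0.242), with the kinase Aurkb at 10.25 ± 0.046 and 10.34 ± 0.080 and the cyclin Ccnb2 at 10.66 ± 0.063 and 10.76 ± 0.16. Genes of DNA replication differed by 0.032 over 16 genes (camera adjusted p = 0.242), with Mcm5 at 11.24 ± 0.036 and 11.31 ± 0.12 and Cdc6 at 8.81 ± 0.078 and 8.90 ± 0.22. The cholesterol synthesis list differed by 0.037 over 19 genes (camera adjusted p = 0.242), with Stard4 at 8.52 ± 0.28 and 8.66 ± 0.063 and Fdps at 10.29 ± 0.22 and 10.39 ± 0.10. In 1 of 19 alternative settings, without control replicate 2, the cholesterol list was called (difference 0.093, camera adjusted p = 9.81e-05). Mitosis was called in 2 of these settings and DNA replication in 1. Glycolysis differed by -0.011 over 15 genes (camera adjusted p = 0.901), with Pfkm at 9.63 ± 0.16 and 9.74 ± 0.091 and Aldoa at 13.35 ± 0.15 and 13.25 ± 0.082. Across the 16 pathway lists, 7 of 293 tested members were at an unadjusted p under 0.05 by limma and 0 passed over all genes or adjusted over the list alone.

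Oocyte transcripts had the same mean level in the groups and a wide spread within each. Over 49 oocyte marker genes the level was 9.17 ± 0.27 (SD, n = 5) in controls and 9.17 ± 0.30 (SD, n = 5) under the Uba3 cKO label (exact two-sided permutation p = 0.992). Single libraries ran from 8.76 in Uba3 cKO replicate 5 to 9.47 in control replicate 3, a range of 1.63-fold. The germ cell and transcription factor list differed by -0.0037, with the opposite sign in the test statistic (camera adjusted p = 0.944), and held Taf4b at 10.23 ± 0.30 and 10.37 ± 0.15 and Figla at 5.36 ± 0.47 and 5.16 ± 0.23. Zona pellucida genes and secreted factors differed by -0.022 (camera adjusted p = 0.881), with Bmp15 at 11.08 ± 0.22 and 11.01 ± 0.22 and Oosp2 at 6.87 ± 0.25 and 6.93 ± 0.18. Maternal-effect genes differed by 0.0086 (camera adjusted p = 0.810), with Pde3a, a phosphodiesterase that breaks down cyclic AMP in the oocyte, at 8.63 ± 0.059 and 8.82 ± 0.25 and Btg4 at 8.74 ± 0.39 and 8.95 ± 0.16. Leaving out 1 library, the maternal-effect difference ran from -0.066 without control replicate 4 to 0.11 without control replicate 3 (camera adjusted p = 0.000417). This list was also called without Uba3 cKO replicate 5 and with library quality weights.

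Follicular somatic cells were likewise close in level. Granulosa markers of growing follicles differed by 0.045 over 16 genes (camera adjusted p = 0.257), with the receptor Npr2 at 12.21 ± 0.11 and 12.30 ± 0.044 and Inhbb, an inhibin and activin subunit, at 14.31 ± 0.30 and 14.60 ± 0.45. Markers of antral granulosa cells differed by -0.0018, with the opposite sign in the test statistic (camera adjusted p = 0.944), and held Grb14 at 13.15 ± 0.23 and 12.96 ± 0.54 and Nppc at 8.54 ± 0.41 and 8.70 ± 0.31. Theca and steroidogenic markers differed by -0.019 (camera adjusted p = 0.901), with Insl3 at 3.58 ± 0.27 and 3.47 ± 0.084 and Hsd3b1 at 13.52 ± 0.49 and 13.72 ± 0.24.

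Stromal, vascular and immune markers varied between libraries of both groups. Fibroblast and matrix genes differed by 0.024 (camera adjusted p = 0.881), with the collagen cross-linking enzyme Lox at 10.11 ± 0.18 and 9.87 ± 0.22 and Fn1 at 9.57 ± 0.35 and 9.34 ± 0.37. Smooth muscle and pericyte genes differed by -0.052 (camera adjusted p = 0.644), with Des at 7.22 ± 0.57 and 6.94 ± 0.21 and Tagln at 4.73 ± 0.19 and 4.61 ± 0.17. Endothelial genes differed by 0.072 (camera adjusted p = 0.242), with Tek at 6.74 ± 0.24 and 6.94 ± 0.28 and Flt1 at 6.26 ± 0.24 and 6.39 ± 0.45. Leaving out 1 library, the endothelial difference ran from -0.039 without Uba3 cKO replicate 4 to 0.17 without Uba3 cKO replicate 3 (camera adjusted p = 0.00211). This list was also called without Uba3 cKO replicate 5 (0.16, camera adjusted p = 0.00865). Macrophage genes differed by -0.042 (camera adjusted p = 0.40), with Mrc1 at 6.47 ± 0.24 and 6.68 ± 0.35 and C1qb at 6.57 ± 0.20 and 6.46 ± 0.20. Without control replicate 2 the macrophage list was called (-0.095, camera adjusted p = 0.0232).

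Markers of the surface epithelium, of adhering tissues and of blood were represented unevenly in single libraries. Surface epithelium genes differed by -0.040 (camera adjusted p = 0.810), with Lgals7 at 8.77 ± 0.47 and 8.62 ± 0.24 and Muc16 at 8.32 ± 0.30 and 8.23 ± 0.53. Leaving out 1 library, the surface difference ran from -0.17 without control replicate 1 (camera adjusted p = 0.00783) to 0.029 without Uba3 cKO replicate 3. Oviduct genes differed by 0.046 (camera adjusted p = 0.810), with Ovgp1, the oviductal glycoprotein, at 4.70 ± 0.35 and 4.83 ± 0.73 and Tmem212 at 3.61 ± 0.14 and 3.63 ± 0.096. For these genes Uba3 cKO replicate 4 stood 0.44 above the mean of all libraries. Without it the oviduct difference turned to -0.058, and without control replicate 1 to -0.012. Adipose genes differed by 0.18 (camera adjusted p = 0.242), with Plin1 at 5.56 ± 0.26 and 5.75 ± 0.39 and Cfd at 5.30 ± 0.66 and 5.74 ± 0.99; Uba3 cKO replicate 2 stood 0.94 above the mean of all libraries, and without it the adipose difference turned to -0.037. Blood genes differed by -0.20 (camera adjusted p = 0.242), with the beta-globins Hbb-bs at 10.28 ± 0.54 and 10.01 ± 0.44 and Hbb-bt at 6.71 ± 0.74 and 6.47 ± 0.29; control replicate 1 stood 1.17 above the mean of all libraries, and without it the blood difference turned to 0.069. The adipose list was called without Uba3 cKO replicate 5 (0.32, camera adjusted p = 0.0191) and with library quality weights. The blood list was called without control replicate 4 (-0.34, camera adjusted p = 0.0168) and without Uba3 cKO replicate 4 (-0.30, camera adjusted p = 0.0406). Across the 14 cell type lists 0 were called in the main comparison. Of 157 tested members 1, Lox, was at an unadjusted p under 0.05 by limma while 0 passed over all genes or adjusted over the list alone.

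**Figure D4:**
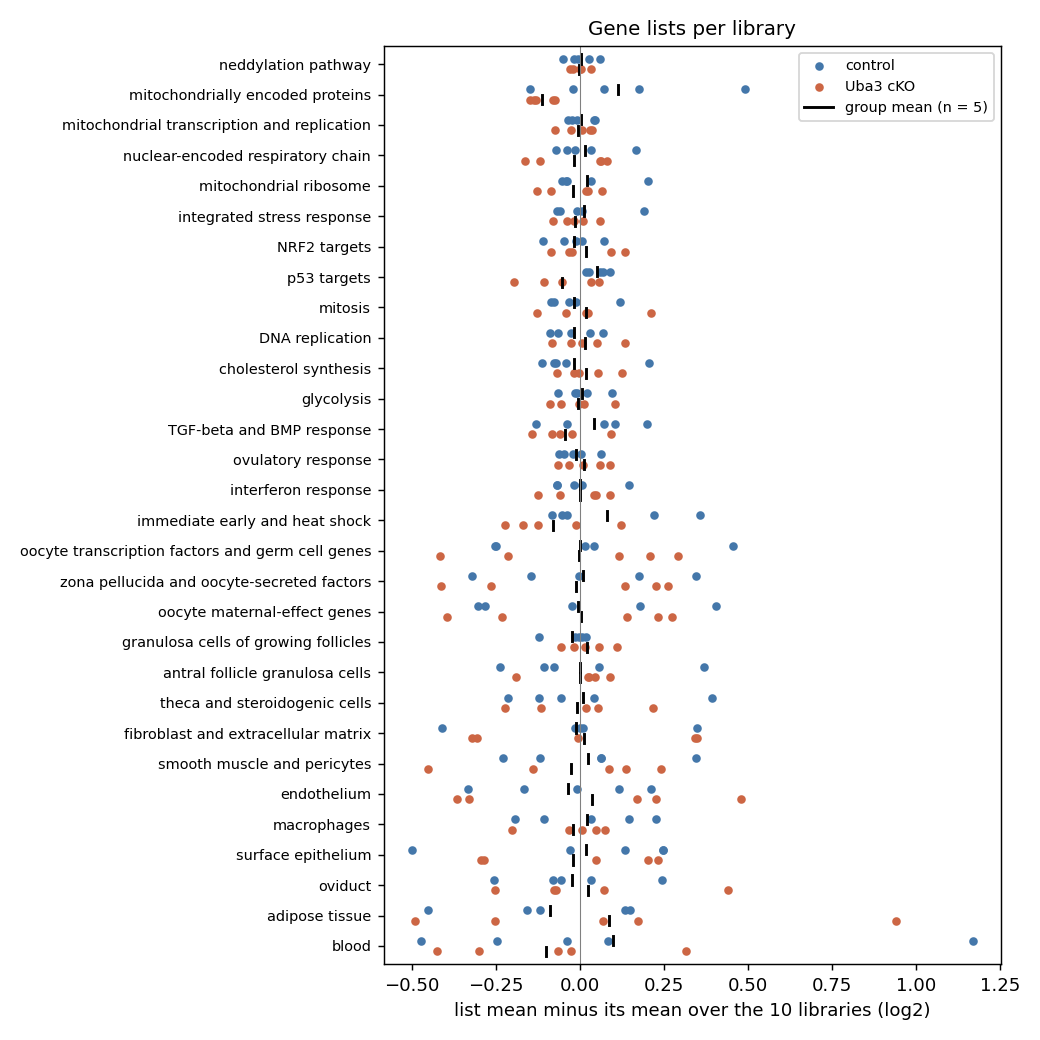
For each of the 30 fixed gene lists, the mean log2 value of its tested genes in each library minus the mean over the 10 libraries, with controls in blue, Uba3 cKO in orange and the group mean (n = 5) as a black bar. The mitochondrially encoded list spreads from -0.15 to 0.49 in controls and from -0.15 to -0.07 under the Uba3 cKO label, and the 3 oocyte lists are spread alike in both groups.

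Genes beside Uba3 on chromosome 6 were tested because the labelled strain is a mix, so that genes linked to the targeted locus could differ by strain of origin. Rab43, a small GTPase, had a log2 difference of 0.32 (standard error 0.13) and Cntn6, a neuronal contactin, of 0.25 (standard error 0.092), each with an adjusted p of 1; both were chosen after their values were seen. Within 10 Mb of Uba3, 0 of 84 tested genes were called by limma. At an unadjusted p under 0.05 there were 2, or 2.38%, against 1.77% of the 15352 genes elsewhere (two-sided Fisher's exact test, p = 0.662).

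A small set of genes lay at 2 separate levels in the libraries without regard to genotype. Gm8730, a processed pseudogene, had values from 7.39 to 7.79 in 6 libraries and from 11.87 to 12.23 in the other 4, which were controls 2 and 3 and Uba3 cKO replicates 1 and 3. Gm14165, Gm9625 and Gm10819 were high in the same libraries, with gaps of 2.70, 2.29 and 1.29 log2 units. Gm14150, Gm3226 and Gm3756 were instead high in control 1 and in Uba3 cKO replicates 4 and 5, with gaps of 1.97, 1.54 and 1.66. In all, 16 genes had a gap of at least 1 log2 unit, and 0 of them split the libraries by group. Of the 16, 13 were annotated pseudogenes and 15 had a near-identical transcript of another gene, so how reads were shared between copies makes their levels uncertain. This set was defined after the values were seen.

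**Figure D5:**
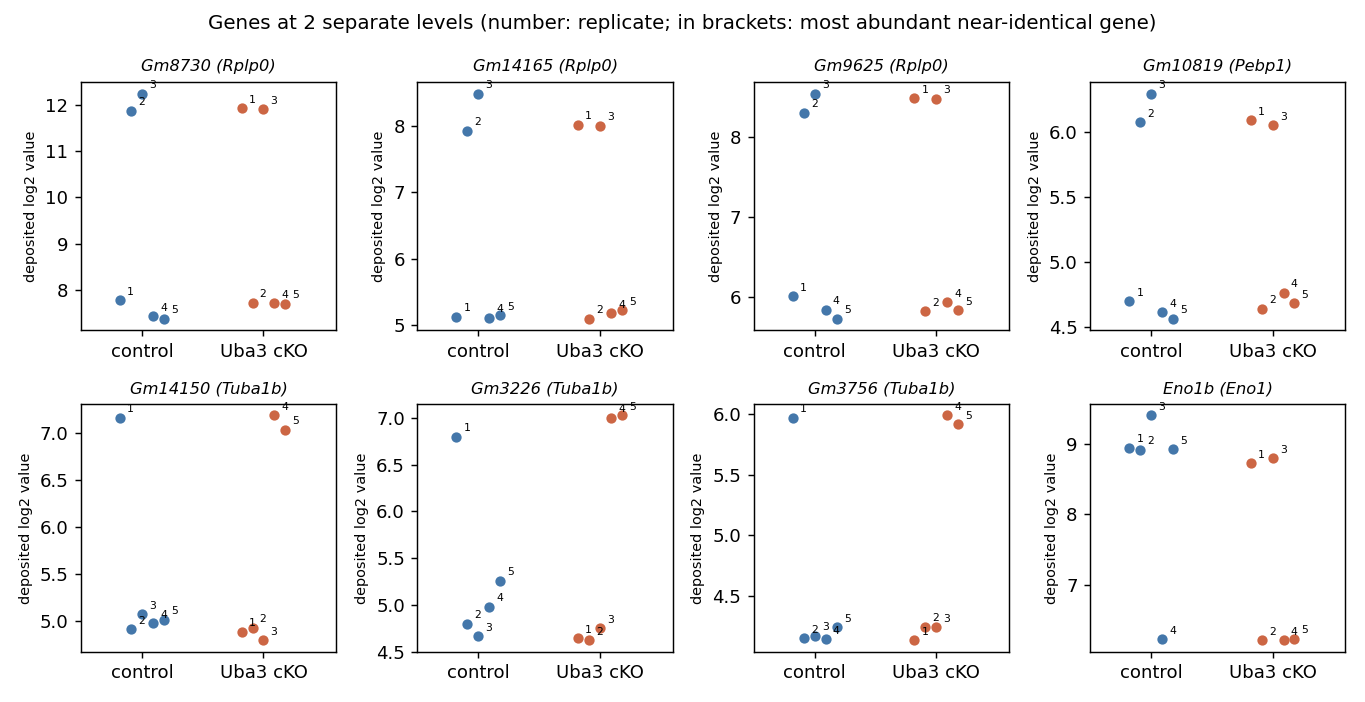
Deposited log2 values in each library, with the replicate number beside each point, for 8 of the 16 genes whose libraries fall at 2 levels; the most abundant near-identical gene is in brackets, and each panel has its own axis, which does not start at 0. The 4 genes of the upper panels are high in the same 4 libraries and those named with Tuba1b in the same 3.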

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

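The tests of control replicate 3 alone, of oocyte content for the mitochondrial list, of genotype and library scaling for the oocyte markers, and of the splits for the count of genes were chosen after the result was seen; the length covariate was chosen after the data were seen but before the result it tests, and the other tests of this part were set before their results.

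Single libraries stood apart from their group of 5 in 10 of 190 groups of values, where chance gives about 9.5, or 1 in 20; the number is the gap to the nearest library as a share of the group's range. Control replicate 3 stood apart in Rbx1 (0.882, at 10.90), in Aldoa (0.714, at 13.61), in the granulosa markers of growing follicles (0.764, a score of -0.12) and in its slope on transcript length (0.784, at -0.18). Control replicate 2 stood apart in cholesterol synthesis (0.776, a score of 0.21) and Gsta4 (0.726, at 9.01), and control replicate 1 in the globin Hbb-bs (0.754, at 11.22). Among libraries labelled Uba3 cKO, replicate 4 stood apart in Npr2 (0.791, at 12.22) and in Ovgp1 (0.749, at 6.10), and replicate 1 in the antral granulosa markers (0.762, a score of -0.19).

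Chance cannot be excluded for the count of lists. Of 100 splits of the 10 libraries into 5 and 5, the real one included, all 100 called at least the real count of 3 lists, with 16 as the highest of the other splits. For genes the real count is 0, which every split reaches by construction, so the comparison says nothing there; the highest of the other splits was 336. At an unadjusted p under 0.05, 85 splits gave at least the 280 genes of the real one. The split with 336 genes set controls 1, 4 and 5 and Uba3 cKO replicates 3 and 5 against the rest, and its sides differed by 0.47 log2 units in the oocyte marker mean, which points to a structure of the samples other than the labelled groups. With the preset correlation, the mitochondrially encoded list was called in 58 of the 100 splits, the immediate early and heat shock list in 45 and the p53 list in 15.

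Mitochondrially encoded transcripts had a lower list mean under the Uba3 cKO label, with a log2 difference of -0.23 (standard error 0.11, exact permutation p = 0.0556). Against control replicate 3 as the whole source, the difference without it was -0.13 (standard error 0.063, exact permutation p = 0.0714), which is 58.4% of the full size. Against a trend with transcript length, the difference with that slope as a covariate was -0.19 (standard error 0.076). Against a difference in oocyte content between the groups, the part of the difference that the oocyte markers can carry (their group difference times the slope on them within groups, at the 95% bounds of that slope) was at most 0.017 log2 units over the 3 oocyte lists and their joint mean. An effect of genotype stays open as a hypothesis, as does chance, since neither the exact test nor the estimated correlation passed the threshold and 58 of 100 splits called the list; a difference in mitochondrial RNA yield between preparations was not tested.

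Oocyte transcripts differed by up to 1.63-fold over the 10 libraries, between Uba3 cKO replicate 5 and control replicate 3. Genotype did not separate them: the group difference was 0.0020 of the SD within groups. Removing the slope on transcript length left 93.3% of the SD, so that trend is not the whole source. Library scaling is not the whole source: a factor per library cancels in the difference of 2 list means, and subtracting the mean of any of the 27 other lists left at least 80.9% of the SD; the neddylation list ran only from -0.051 to 0.059. The share of oocytes in each ovary sample may be the source, as 41 of 49 markers correlated above 0.7 with the mean of the others over the 10 libraries, but no value in these data measures oocyte number.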

How the results depend on the processing

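The covariates and the counts at unadjusted p were chosen after the data were seen; the other alternatives were set before. Uba3, at 0.0032 in the comparison, reversed in sign with library quality weights (-0.048), with the length slope as a covariate (-0.015) and when leaving out 1 library in turn (-0.056 without control replicate 3, to 0.066), always inside its interval. Genes called by limma stayed at 0, with 280 at unadjusted p under 0.05, in all settings but the length slope covariate, which called 1, Dip2c (adjusted p = 0.0142, elsewhere 0.263 to 1); unadjusted counts ran from 133 with a mean of at least 50 to 604 without a filter, and from 198 to 392 leaving out 1 library. Near Uba3 0 were called and 2 were at unadjusted p. The 3 lists became 5 with quality weights, 0 with an estimated correlation and 3 to 8 leaving out 1 library, with at least 5 without controls 1, 2, 4 or 5 or Uba3 cKO replicates 1, 3 or 5. Over 19 settings with the preset correlation, 13 other lists were called at least once, the mitochondrial ribosome in 8 and each other in at most 4. Of the 27 lists not called, 21 turned in sign without at least 1 library, so their directions are not settled; of the 3 called, 0 did. With an estimated correlation the differences of -0.23 (mitochondrially encoded), -0.10 (p53) and -0.16 (immediate early) had camera adjusted p of 0.587, 0.587 and 0.913. The correlations estimated from the data were 0.544, 0.099 and 0.4, against the preset 0.01. Leaving out 1 library the 3 differences ran from -0.29 to -0.13, -0.13 to -0.069 and -0.21 to -0.094. The p53 call ended without Uba3 cKO replicate 4 (-0.069), and the immediate early call without control 3 (-0.094) and with quality weights (-0.097), which gave control 3 a weight of 0.256; the cause was not tested further. Of 1130 values of 60 other named genes, 1119 kept their sign; the 11 that reversed, none of them called, did so without 1 library, over ranges of -0.15 to 0.012 for Bmp15, -0.014 to 0.16 for Oosp2, -0.016 to 0.25 for Flt1, -0.30 to 0.028 for Lgals7, -0.22 to 0.058 for Muc16, -0.18 to 0.26 for Ovgp1, -0.030 to 0.055 for Tmem212 and -0.41 to 0.060 for Hbb-bt. The replicate block gave 0 genes, 311 at unadjusted p and 4 lists, with the TGF-beta and BMP response as the added list. Same-number correlations ran from -0.27 to 0.28, 2 of 5 above 0.1, and 2 of 10 libraries matched their own number best. These values cannot settle whether the numbers pair the samples, and the labels do not say that they do. Other pseudocounts and the edgeR and DESeq2 tests were not run: the values are log2 and hold no counts. Depth is unknown, so its limit cannot be stated.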

Other observations

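The test of genotype was chosen after the result was seen, and so was the comparison of pairs by their abundant copies in the first 16 genes; the tests of shared reads, of neighbouring genes and of further pairs were set before their results.

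The most abundant near-identical genes of the 2-level set had mean levels from 9.94 to 15.50. Gm8730, Gm14165 and Gm9625, on chromosomes 8, 2 and 13, are copies of Rplp0, a ribosomal stalk protein with the highest of these levels. Gm14150, Gm3226 and Gm3756, on chromosomes 2, 13 and 9, are copies of the alpha-tubulin Tuba1b, with a mean of 13.72. Eno1b is a copy of the glycolytic enzyme Eno1 (13.00), Gm4737 of Ahcy (11.28), Gm10036 of Rpl11 (14.31), Gm13841 of Rpl29 (13.06) and Gm10819 of Pebp1 (12.63). Lower levels belonged to Fabp5 (10.92, with the copy Gm6166), Psmb5 (10.41, Gm3375), Ncoa4 (10.24, Gm6768) and Tdg (9.94, Gm9855). Ptprv, with a gap of 1.08, was the 1 gene of the 16 with no near-identical transcript.

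Genotype does not account for the 2 levels, since 0 of the 16 genes split the libraries by group. Reads shared between copies may account for them, but the comparison made cannot decide it. A near-identical transcript of another gene was found for 93.8%, against 2.53% of 79 genes matched on mean level (Fisher's exact test, p = 1.93e-14). That test counts the 16 genes as independent, although 6 share their abundant copy and their split with another, so its p may be too small. Gene class was not matched: 13 of the 16 were annotated pseudogenes, against 2.65% of the other tested genes. Pseudogenes that did not lie at 2 levels were not compared. Whether neighbours on a chromosome share their split is open, because only 1 pair lay within 10 Mb. Pairs with the same abundant copy, or with copies within 10 Mb, split the libraries identically in 9 of 9 pairs, against 0 of 96 others. Of the 9, 6 had the same copy and 3 joined Pebp1 with Rplp0 on chromosome 5. The 9 pairs are not independent. They join only Gm8730, Gm14165, Gm9625 and Gm10819 with each other, or Gm14150, Gm3226 and Gm3756. All 3 pairs with Pebp1 rest on the gene Gm10819. These shared splits raised the hypothesis below. Variants at the abundant genes, segregating in the mixed strain, may send some of their reads to the copies, but this stays untested: among 10 further genes with gaps from 0.5 to 1, 1 per abundant copy, 0 pairs had neighbouring abundant copies.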
